A study of Mus musculus with 2 samples.

How the data were processed

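The data are droplet single-cell RNA profiles of CD45-positive liver cells from recipients of Trem2-/- or Trem2+/+ marrow, with 1 library per group and 4 mice combined in each. Per the labels' protocols, the cells were released with a mouse liver dissociation kit, sorted as viable CD45-positive cells and captured with 10x Genomics 5' chemistry, in which reads start at the 5' ends of transcripts and each molecule is counted once by its molecular identifier (UMI). The deposited values are raw UMI counts per gene and barcode in matrices of 32285 genes, made with Cell Ranger 5.0.1 per the file headers, against mm10 per the submitters' processing notes. The other deposited files hold gene names and barcode names in the same order. The annotation release behind the counts is not given in the sources used here. Of the 32285 gene identifiers, 32158 (99.6%) were found in GENCODE release M21 of mm10, from which coordinates and exons were taken. No cell type annotation by the authors was used here.

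Groups were taken from the genotype label of each sample. Gene lists, markers, named-gene rule, filters and the alternatives to try were fixed before the data were examined, except where stated. Cells with at least 200 genes and at most 10% mitochondrial UMIs that were not called doublets were kept: 5973 of 6362 barcodes in the Trem2-/- library (93.9%) and 6596 of 7012 (94.1%) in the Trem2+/+ library. Doublets were called with Scrublet in each library at an expected rate of 0.06. It marked 5 barcodes (0.0786%) and 2 barcodes (0.0285%), under 0.5% of 13374, so doublet calling had not worked, and the kept cells should be read as holding doublets. An alternative without the 5% of barcodes with the highest scores was therefore added after the data were seen. Kept cells had medians of 1307 and 1115.5 detected genes and 1.56% and 1.41% mitochondrial UMIs; 847 and 1132 of them had under 1000 UMIs. The libraries shared 56 barcode sequences.

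Genes seen in at least 10 cells were used for clustering. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen across both libraries without Trem2 and its Trem and Treml neighbours, and 30 principal components, 15 neighbours and Leiden resolution 1 were used, with no batch integration because library and genotype coincide. Clusters were named "-like" from markers of 25 classes: the class with the highest mean log2 fold over all its markers, with at least 3 markers detected in at least 0.2 of the cells. A cluster stayed unnamed when its median UMI count was under 0.3333 of its library's and none of the class's markers was among its top 10 genes. Further naming limits were set after the clusters and their sizes had been seen: a mean marker log2 fold of at least 0.5, no name where a competing class reached 0.7 of the leading fold with at least 5 markers, and no innate lymphoid type 2 name where Cd3e was detected. Pairs of related classes, such as Kupffer-like and macrophage-like, were exempt from the 0.7 limit. A cluster whose top 10 genes held more markers of another class also got no name. Clusters 9, 12, 18 and 22 were left unnamed, with 0.820%, 6.18%, 3.78% and 3.45% of kept cells in the Trem2-/- library and 0.531%, 2.91%, 4.02% and 1.26% in the Trem2+/+ library, and cluster 21 (1.00% and 0.243%) was placed with T cells. Shares of the CD4 and CD8 clusters were computed but are not reported, because genes that lead some of those clusters, such as Pdcd1, Tigit and Ctla4, differed between the libraries.

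No test was made between the groups, since cells of 1 library are not replicates. Shares of cells have exact binomial intervals, and ratios of shares large-sample intervals for a ratio of proportions. UMIs were summed per library and class and divided by the class total (CPM), with exact Poisson intervals; ratios of sums have exact conditional binomial intervals. Ratios are given for the 10 classes with at least 100 cells in each library, clusters summed. Named genes are the 12 highest and 12 lowest log2 ratios in macrophage-like cells, and the 4 highest and 4 lowest in each other class, among genes with a mean of at least 100 CPM, at least 100 UMIs over both libraries and a ratio of at least 1.5-fold. Left out of that ranking were Trem2, receptor and immunoglobulin segment genes, haemoglobin, mitochondrial, ribosomal protein, sex-linked and hepatocyte genes, predicted genes without a name, and genes whose CPM in the class was under 0.2 of that in another class of the same library. Some genes named by this rule are not reported here. Members of the fixed lists may be named at any size. The receptor beta segments, the Cxcl9 values outside the size rule and the clusters described singly were chosen after their values were seen.

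For 29 gene lists, the median log2 ratio of members with a mean of at least 20 CPM was computed where the class fits the list, with an interval from Poisson resampling of the counts and its percentile among 10000 random lists of the same size matched on mean expression (seed 1). Of these 130 medians, 33 lay above and 22 below the central 95% of their random lists; those given in the text were selected after all had been seen, and the percentiles are not corrected for that. Shares of cells with a Trem2 UMI were also computed after thinning each cell to 1000 or 2000 UMIs without the shallower cells. A count of 0 allows up to 3 counts.

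The statistics were tested on counts simulated from the real means and totals with known ratios. That test was written after the first run on the real data. For macrophage-like, Kupffer-like and T cell-like classes, intervals held the truth for 95.2%, 95.4% and 96.2% of unchanged genes and for 97.0%, 100.0% and 87.9% of genes planted at 4-fold. Of 200 unchanged lists of 20 genes, 5.0%, 5.0% and 5.5% fell outside the central 95% of random lists, and 100.0% of 50 lists planted at 1.5-fold lay above it. The draws were independent Poisson counts and the lists random genes, the model that the intervals and percentiles assume. The test thus checks the calculation and does not cover lists whose members vary together.

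The alternatives were all deposited barcodes (except the called doublets, here and wherever this setting is named), stricter filters (500 genes, 5% mitochondrial UMIs), doublets kept, Leiden resolutions 0.5 and 2, each library clustered alone, list genes kept out of clustering, trimmed-mean (TMM) scaling with edgeR, a total without hepatocyte, haemoglobin, mitochondrial, ribosomal and immunoglobulin genes, the mean over cells, other CPM limits, thinning, shares without neutrophils or B cells, and shares among cells with at least 1000 UMIs. Added after the data were seen were removal of the top 5% of doublet scores, clustering without the macrophage and MHC class II lists, equal weight for the clusters of a class, and ratios from cells with at least 1000 UMIs. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were used, with R 4.3.3 and edgeR 4.0.16.

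These steps bear on the values in several ways. With 1 library per group, differences between mice, sorts or capture runs are part of every ratio. Droplets hold free RNA and some hold more than 1 cell, which puts transcripts of abundant classes into others. The class total sets the scale of each CPM, so a few abundant genes shift all ratios of a class. Names were rebuilt from clusters, so class borders can differ from those of the study.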

Results

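Liver leukocytes were profiled cell by cell in male C57BL/6J mice with diet-induced steatohepatitis whose blood-forming cells had been replaced by donor marrow. The recipients were irradiated and given marrow from Trem2-/- donors or from Trem2+/+ littermates, recovered for 6 weeks, and were then fed for 4 weeks on a diet lacking methionine and choline, which produces fatty, inflamed livers. Viable cells carrying CD45, the surface protein shared by leukocytes, were sorted after enzymatic dissociation, and equal parts from 4 mice per group were combined before droplet capture. Each group is therefore 1 library read from the 5' ends of transcripts, so no difference below has a replicate check, and the 4 mice of a pool were not separated. The comparison asks how loss of TREM2 from marrow-derived cells alters the composition and transcription of liver leukocytes in this model.

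The Trem2-/- library held 6362 barcodes with 25288032 deduplicated transcript counts (UMIs), and the Trem2+/+ library 7012 barcodes with 27238586 UMIs. After filtering, 5973 and 6596 cells remained, with medians of 2932 and 2492 UMIs per cell. Levels are in CPM, the UMIs of a gene scaled to a fixed class total, and log2 ratios are the Trem2-/- library over the Trem2+/+ library, so values below 0 are lower in the Trem2-/- library. All intervals are 95% intervals and cover counting error only, not the variation between mice. Of the gene lists fixed in advance, 130 list medians were computed over 10 cell classes. The position of a median among 10000 random lists of equal size and matched expression describes these libraries alone.

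Trem2 transcripts were nearly lost from the Trem2-/- library, in the direction of its label. Trem2 (ENSMUSG00000023992), a lipid-binding receptor of macrophages, lies on chromosome 17 of mm10 from 48346401 to 48354147 on the forward strand, and its transcript Trem2-201 has 5 exons. Over all kept cells the library held 154 Trem2 UMIs, or 6.19 CPM (exact Poisson interval 5.25 to 7.25), against 5478 UMIs, or 204 CPM (199 to 209.6), in the Trem2+/+ library. The log2 ratio was -5.04 (-5.28 to -4.81), which left the Trem2-/- library at 3.03% of the Trem2+/+ level. That percentage also takes in the smaller share of macrophage-like cells in the Trem2-/- library. Within macrophage-like cells the level was 7.54% of that in the Trem2+/+ library, and within Kupffer-like cells 7.42%. Which part of the gene was deleted is not given in the sources used here, and 5' reads from an undeleted part would be counted as Trem2.

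The difference held in each class of mononuclear phagocytes. Macrophage-like cells carried 50.7 CPM (41.2 to 61.8) in the Trem2-/- library and 673 CPM (653.6 to 693.8) in the Trem2+/+ library, a log2 ratio of -3.73 (-4.03 to -3.44). Kupffer-like cells, which resemble the resident macrophages of the liver, carried 26.0 CPM (15.9 to 40.1) and 349.8 CPM (305 to 399.8), a log2 ratio of -3.75 (-4.49 to -3.09). In Ly6C-high monocyte-like cells the levels were 5.93 CPM (3.62 to 9.16) and 151 CPM (139.8 to 163), a log2 ratio of -4.67 (-5.39 to -4.03). At least 1 Trem2 UMI was seen in 19.1% (14.5 to 24.4) of macrophage-like cells of the Trem2-/- library, at a median depth of 7022 UMIs, and in 62.9% (59.9 to 65.8) of those of the Trem2+/+ library, at 4698 UMIs. In T, B, NK and neutrophil classes, which should lack the gene, the shares were 0.115% at a median of 2677.5 UMIs and 0.935% at 2119 UMIs. With every cell thinned to 1000 UMIs, the macrophage-like shares were 5.86% of the 222 cells deep enough and 40.6% of 833 such cells, out of 257 and 1094.

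Within the Trem2+/+ library, most Trem2 transcripts came from mononuclear phagocytes. Macrophage-like cells held 79.5% of its Trem2 UMIs, monocyte-like cells 12% and Kupffer-like cells 3.93%. Stellate or fibroblast-like cells stood at 88.2 CPM from only 8 UMIs, cells without a class name at 78.4 CPM and cycling cells at 55.8 CPM, while endothelial-like cells stood at 13.4 CPM, neutrophil-like cells at 8.66 CPM, type 2 conventional dendritic-like cells (cDC2) at 7.93 CPM, B cell-like cells at 5.09 CPM and T cell-like cells at 1.72 CPM. No UMI was found in 74 plasmacytoid dendritic-like cells. The share of cells with a UMI was 40.3% in Kupffer-like cells at a median depth of 1251.5 UMIs and 38.0% in monocyte-like cells at 6283 UMIs. Thinned to 1000 UMIs, these shares were 26.1% and 12.6%, against 0.257% in the T, B, NK and neutrophil classes. Among the 3 clusters of the macrophage-like class, the level was 783 CPM in cluster 19, 549 CPM in cluster 15 and 339 CPM in cluster 16.

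**Figure D1:**
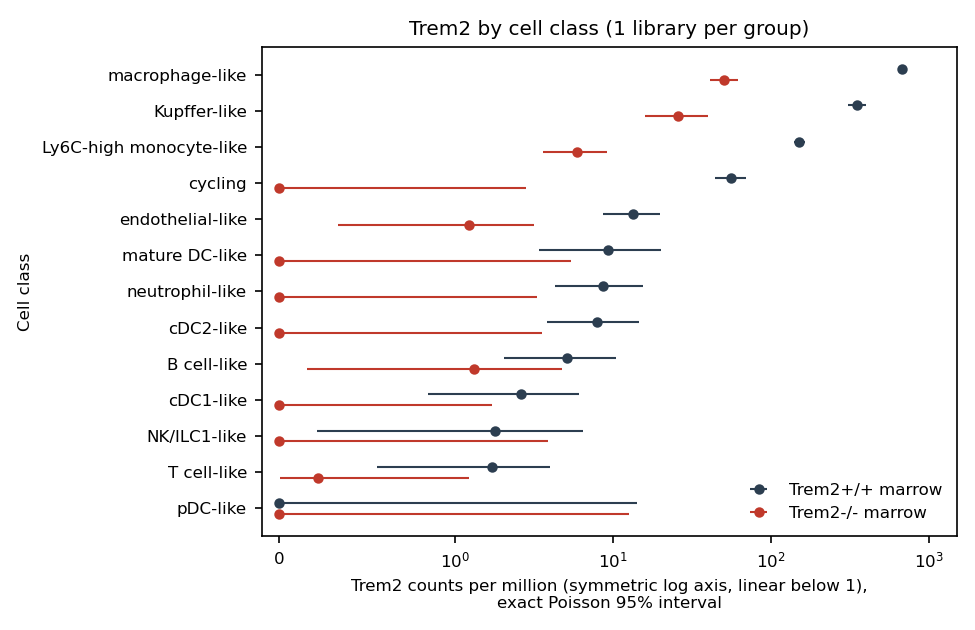
Trem2 level in CPM (horizontal axis, logarithmic above 1 and linear below) in 13 cell classes of the Trem2-/- and Trem2+/+ libraries; points are the level of 1 library and lines the exact Poisson 95% interval. Macrophage-like cells stand at 673 CPM in the Trem2+/+ library and at 50.7 CPM in the Trem2-/- library.

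Of the Trem and Treml genes beside Trem2 on chromosome 17, Trem3 was the one that differed most over all kept cells. Trem3 (48247777 to 48258841) was lower in the Trem2-/- library over all kept cells, at 11.3 against 23.2 CPM, a log2 ratio of -1.03 (-1.24 to -0.83); within neutrophil-like cells, its main source, the levels were 155 (132.8 to 179.8) and 245 CPM (218 to 273.7). Trem1, an amplifier of myeloid inflammation (48232768 to 48246924), stood at 42.7 and 41.0 CPM with a log2 ratio of 0.06. The all-cell ratios were -0.40 for Treml4 (48264295 to 48275360) and -0.17 for Treml2 (48299498 to 48312533). By class, Treml4 stood at 0.31 (0.08 to 0.54) in macrophage-like, 0.45 (0.05 to 0.85) in Kupffer-like, 0.02 (-0.18 to 0.22) in monocyte-like and -0.76 (-1.29 to -0.26) in neutrophil-like cells. Treml1 (48359916 to 48367176) had 5 and 3 UMIs, too few for a comparison. Tyrobp, the adaptor through which TREM2 signals, was close in macrophage-like cells of both libraries at 2898 and 3238 CPM (log2 ratio -0.16, -0.20 to -0.12), and the 19 measured TREM2 partners and signalling genes had a median of 0.13 (0.05 to 0.24; percentile 99.0), with none past 1.5-fold either way. In Kupffer-like cells the median of 18 such genes was -0.16 (-0.23 to 0.07; percentile 1.24), with 11 below 0. The genes past 1.5-fold there, picked out after their values were seen, were Vav3 (0.67, -0.49 to 1.93; -0.52 at Leiden resolution 2) and Cd33 (-0.69, -1.58 to 0.19). Over the alternatives the list median ranged from -0.08 to 0.18 in macrophage-like and from -0.19 to 0.13 in Kupffer-like cells.

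Macrophage-like cells took a much smaller share of the Trem2-/- library. They were 4.30% of its kept cells (exact binomial interval 3.802 to 4.85; 257 cells) and 16.6% of the Trem2+/+ cells (15.7 to 17.5; 1094 cells), a log2 ratio of -1.95 (-2.14 to -1.76). Ly6C-high monocyte-like cells were also lower, at 7.79% against 10.4% (log2 ratio -0.42, -0.59 to -0.26), whereas Kupffer-like cells stood at 3.87% and 3.91% (-0.02, -0.27 to 0.23). The 3 classes together were 16.0% (15.03 to 16.9) and 30.9% (29.8 to 32.1), a log2 ratio of -0.96 (-1.05 to -0.86). Cluster 16 of the macrophage-like class had a median of only 686 UMIs per cell, and among cells with at least 1000 UMIs the macrophage-like ratio was -1.82 (-2.02 to -1.61). Some genes that name these classes, among them Gpnmb, Fabp5 and Cd63, also differed between the libraries; clustering without the macrophage and MHC class II lists gave -0.96 for the pooled share and -1.49 for macrophage-like cells, and turned the monocyte ratio to 0.22. Clustering each library alone gave no macrophage-like cluster in the Trem2-/- library, with a ratio of 2.0 for Kupffer-like cells and -0.59 for the pooled share.

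T cells and endothelial cells took larger shares in the Trem2-/- library. T cell-like cells were 19.3% (18.3 to 20.3) against 12.2% (11.5 to 13.1), a log2 ratio of 0.66 (0.54 to 0.78), which became 0.13 when each library was clustered alone. Endothelial-like cells were 16.3% (15.4 to 17.3) against 10.2% (9.50 to 11.0), a ratio of 0.68 (0.54 to 0.81); they passed a CD45 sort but had 64.1 and 84.0 CPM of Ptprc, which encodes CD45, against 1047 and 979.8 CPM in T cell-like cells. B cell-like cells were 12% and 11.8% (0.03, -0.11 to 0.16) and natural killer and innate lymphoid type 1 (NK/ILC1)-like cells 3.63% and 4.25% (-0.22, -0.48 to 0.03), a ratio that turned to 0.22 at Leiden resolution 2. Neutrophil-like cells were 8.77% and 10.6% (-0.28, -0.43 to -0.12), a direction that turned to 0.67 when each library was clustered alone. Ratios for dendritic classes had intervals that included 0, with -0.13 (-0.41 to 0.15) for type 1 conventional dendritic-like cells (cDC1), -0.26 (-0.60 to 0.08) for cDC2-like cells and 0.04 (-0.37 to 0.44) for mature dendritic-like cells, and the last fell to -1.45 with each library clustered alone. Clusters left without a name held 14.2% and 8.72% of cells, of which clusters 12 and 22, both led by lymphoid genes, held 9.63% and 4.17%. Because these are shares of sorted cells, they say nothing of cell numbers per liver.

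**Figure D2:**
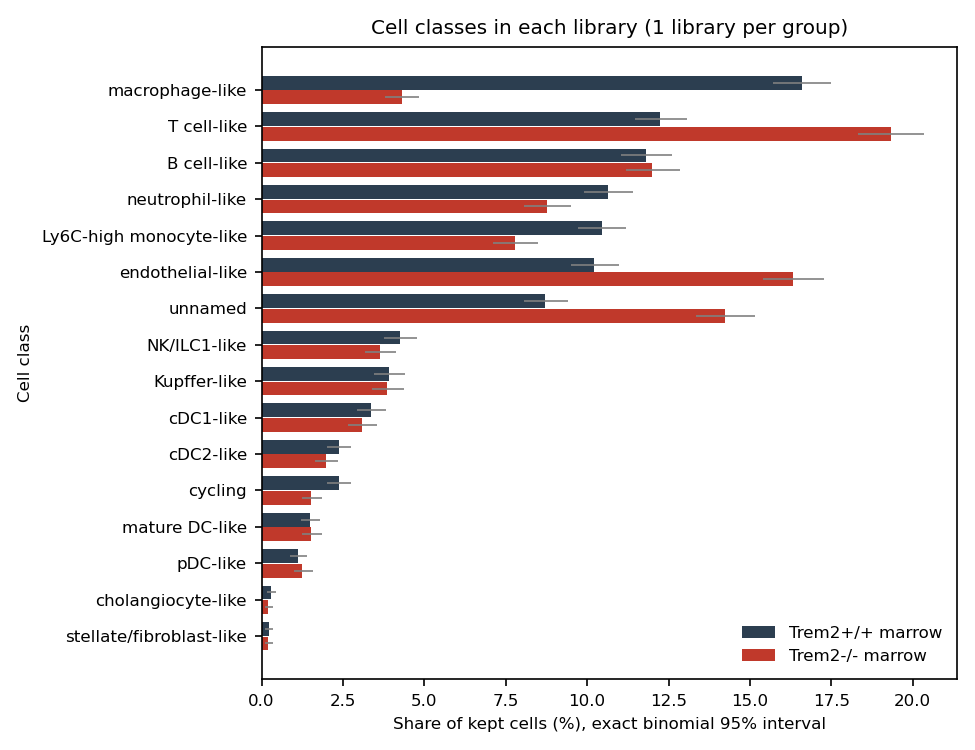
Share of kept cells in percent (horizontal axis) for each cell class in the Trem2-/- and Trem2+/+ libraries; bars are the share in 1 library and lines the exact binomial 95% interval. Macrophage-like cells are 4.30% against 16.6%, and T cell-like cells 19.3% against 12.2%.

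Macrophage-like cells of the Trem2-/- library had lower transcript levels of the lipid-associated macrophage genes, and higher levels of MHC class II and chemokine genes. Lowest by the size rule were Cd36, a scavenger receptor for fatty acids and oxidised lipoproteins (272 against 619.9 CPM, log2 ratio -1.19, -1.32 to -1.06), and the fatty acid carrier Fabp5 (ENSMUSG00000027533, chromosome 3, 10012548 to 10016607; 818 against 1761 CPM, -1.11, -1.18 to -1.03). The glycoprotein gene Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929) stood at 856 against 1794 CPM (-1.07, -1.14 to -0.99), and the elastase gene Mmp12 at 569.5 against 1173 CPM (-1.04, -1.13 to -0.95). The others on the lower side were Anxa1 (-1.10), Alas1 (-1.04), Lgals1 (-0.94), the lipoprotein lipase gene Lpl (-0.91), Gstm1 (-0.85), the galectin-3 gene Lgals3 (-0.81), Prdx1 (-0.73) and Anxa2 (-0.69). With the clusters weighted equally, Anxa2 turned to 0.29, and Alas1 and Anxa1 stood at -0.36 and -0.46. The class was held by the same clusters in other proportions: clusters 15, 16 and 19 made up 50.2%, 19.8% and 29.96% of it in the Trem2-/- library and 30.1%, 31.4% and 38.5% in the Trem2+/+ library.

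Highest by the size rule were the heat shock gene Hspa1a (167 against 59.7 CPM, log2 ratio 1.48, 1.26 to 1.70) and Cxcl9, an interferon-gamma-induced chemokine that attracts T cells (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079; 166 against 69.2 CPM, 1.26, 1.05 to 1.47). The MHC class II chain gene H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674) stood at 5627 against 3353 CPM (0.75, 0.71 to 0.78). The others on this side were Ly6a (0.89), the chemokine gene Cxcl10 (0.85), Tmem176a (0.84), Cd72 (0.75), Lyz1 (0.73), Cd81 (0.70), Egr1 (0.69), the adhesion molecule gene Vcam1 (0.69) and Tmem176b (0.68). Among these, Cd72 turned to -1.04, Cd81 to -0.27 and Vcam1 to -0.11 when all deposited barcodes were used, and Lyz1 to -0.09 with stricter cell filters.

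The lipid-associated macrophage genes were lower as a group. Their median log2 ratio was -0.56 (-0.66 to -0.53), below all 10000 matched random lists, with 12 of 25 measured members at least 1.5-fold lower and none at least 1.5-fold higher. Beyond those named above, Fabp4 stood at -2.00 (-2.30 to -1.71), the collagen-degrading protease gene Ctsk at -1.72 (-2.44 to -1.07) and Cd63 at -0.65 (-0.73 to -0.58), while the apolipoprotein gene Apoe, at 0.20 (0.19 to 0.22), was the single member above 0. Within clusters 15, 16 and 19 the list medians were -0.18, -1.0 and -0.29. Gpnmb was lower in each of these clusters, with ratios of -0.57, -2.08 and -0.52, whereas Fabp4 stood at 0.58 (-0.07 to 1.21), -0.99 (-2.50 to 0.24) and -1.99 (-2.38 to -1.62). Fabp4 was left out of the size ranking because its level was under 0.2 of that in another class of the same library. It led the top genes of endothelial-like cluster 1, so free RNA or doublets could give part of its level. Iron and oxidative stress genes were lower too, with a median of -0.50 (-0.59 to -0.41), below all random lists, and 5 of 12 members at least 1.5-fold lower. Within clusters 15, 16 and 19 this median was -0.18, -0.57 and -0.20. The members included Hmox1, which degrades heme (-0.66, -0.78 to -0.54), the ferritin gene Fth1 (-0.66, -0.68 to -0.64) and the cystine transporter gene Slc7a11 (-0.65, -0.90 to -0.40). The iron exporter gene Slc40a1 was at 0.03 (-0.10 to 0.15). With all deposited barcodes, Apoe turned to -0.43 and Slc7a11 to 0.03.

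Antigen presentation genes were higher, with a median of 0.56 (0.45 to 0.61), above all random lists, and 7 of 14 members at least 1.5-fold higher. The class II genes H2-Aa and H2-Ab1 and the invariant chain gene Cd74 stood at 0.62, 0.62 and 0.61, and the class II transactivator gene Ciita at 0.73 (0.43 to 1.02), while the class I gene H2-D1 was at 0.03 (-0.01 to 0.08). Within clusters 15, 16 and 19 the medians were 0.24, 0.81 and 0.57. Inflammatory cytokine and chemokine genes had a median of 0.35 (0.20 to 0.45), above all random lists, with 7 of 23 members at least 1.5-fold higher and none as far lower. Besides the chemokines above they included Ccl12 (1.33, 0.81 to 1.83), Il1a (1.18, 0.90 to 1.45) and the inflammasome sensor gene Nlrp3 (0.70, 0.44 to 0.96), while Ccl9 was at -0.34 (-0.48 to -0.21). Within the clusters the inflammatory median was 0.26, -0.56 and 0.47. Interferon-response genes had a median of 0.28 (0.16 to 0.35), above all random lists, with 3 of 24 at least 1.5-fold higher, among them Igtp (0.95) and Oasl1 (0.71). Dissociation stress genes, which can be induced while tissue is digested, moved the same way, with a median of 0.23 (0.17 to 0.27), above all random lists, 19 of 20 members above 0 and 4 at least 1.5-fold higher, and within the clusters their median was 0.36, -0.71 and 0.39. Ccl12 turned to -1.38 with all deposited barcodes, Oasl1 to -0.22 with the macrophage and MHC class II lists out of clustering, and Nlrp3 to -0.03 as a mean over cells.

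**Figure D3:**
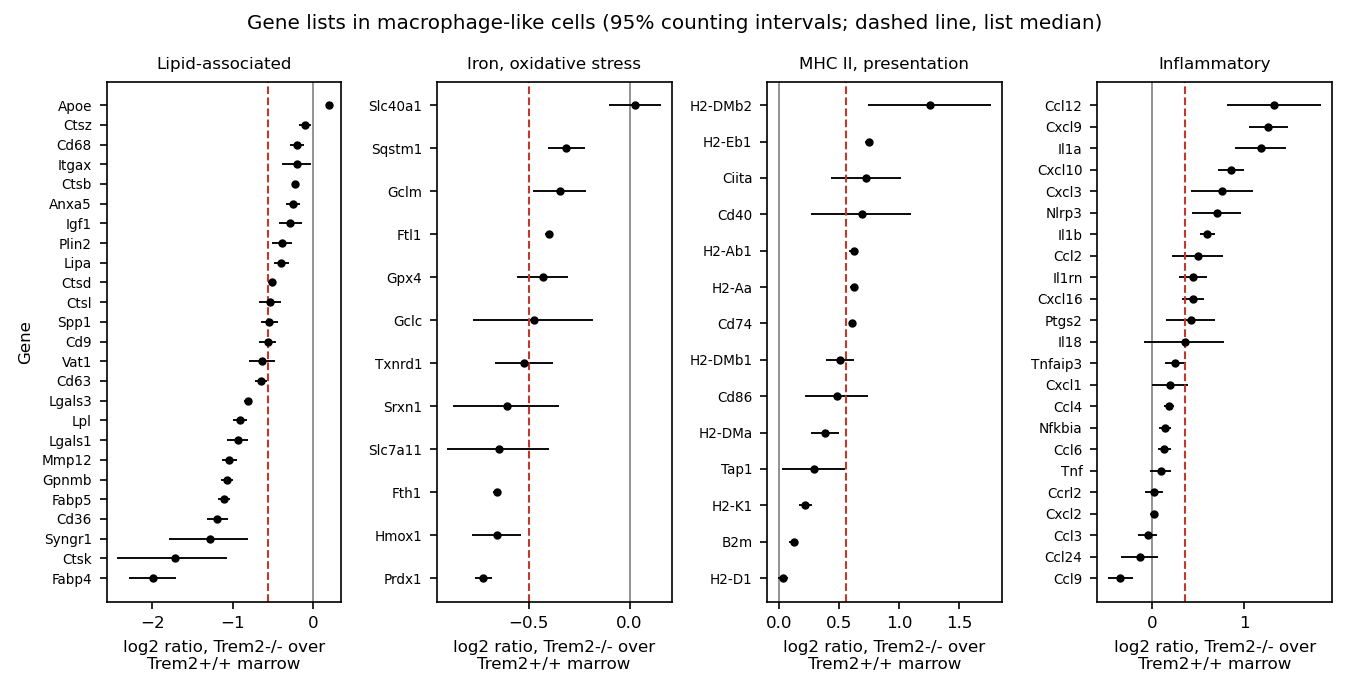
Log2 ratio of the Trem2-/- over the Trem2+/+ library in macrophage-like cells (horizontal axis) for the measured genes of 4 lists, 1 panel per list; points are genes, solid lines their 95% counting intervals and dashed lines the list medians. The medians are -0.56 for lipid-associated macrophage genes, -0.50 for iron and oxidative stress genes, 0.56 for antigen presentation genes and 0.35 for inflammatory genes.

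Cell cycle genes had a median of 0.35 (0.09 to 0.58, percentile 99.9) in macrophage-like cells. Of 7 measured members, 6 were above 0 and 3 at least 1.5-fold higher, and this list was not followed over the alternatives. The lists that follow moved less, and they share members with those above. Cd36, Fabp4, Fabp5 and Lpl of the lipid uptake list are also lipid-associated macrophage genes. So are Mmp12 and Ctsk of the matrix list and Cd63 of the lysosome list. Likewise, Cxcl10 is in both the inflammatory and the interferon-response list. The list medians are thus not independent of each other. Lysosome genes had a median of -0.11 (-0.17 to -0.08), at percentile 0.26 of the random lists, with 2 of 29 members at least 1.5-fold lower, the proton pump subunit gene Atp6v0d2 (-1.21) and Cd63. Lipid uptake, storage and efflux genes had a median of -0.09 (-0.25 to -0.04; percentile 3.09), with 5 of 23 at least 1.5-fold lower, among them the oxidised lipoprotein receptor gene Olr1 (-0.88); the cholesterol exporter genes Abca1 and Abcg1 stood at -0.08 and 0.01. Matrix turnover genes had a median of -0.14 (-0.20 to -0.07; percentile 0.45), with 5 of 18 at least 1.5-fold lower, including Adam8 (-1.49, but -0.11 with the clusters weighted equally) and Mfge8, which bridges dying cells to phagocytes (-3.42, -4.30 to -2.66; -1.43 as a mean over cells). Efferocytosis and complement genes had a median of 0.18 (0.13 to 0.28; percentile 99.9), with C1qa at 0.42 and C1qc at 0.40. Resident Kupffer identity genes had a median of 0.14 (0.04 to 0.28; percentile 98.5), with the complement receptor gene Vsig4 at 1.02 (0.86 to 1.19). With all deposited barcodes the efferocytosis median turned to -0.26, the Kupffer identity median to -0.36, C1qa to -0.26, C1qc to -0.47, Vsig4 to -1.05 and Olr1 to 0.25, and with the clusters weighted equally the interferon-response median turned to -0.16 and the stress median fell to 0.08. RNA of other cell types was similar in both libraries, at 429.6 and 497 CPM summed over hepatocyte genes and 265 and 226 CPM over neutrophil genes. On counts simulated for 1362 genes of this class, the intervals held the true ratio for 95.2% of unchanged genes, and 47.1% of genes planted at 1.5-fold and 100% of those at 2-fold passed the 1.5-fold limit.

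Kupffer-like cells of the Trem2-/- library had far more Cxcl13, a chemokine that attracts B cells, and less Cd163, Timd4, Pf4 and Marco. Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068) stood at 638 against 114 CPM, a log2 ratio of 2.48 (2.12 to 2.87), which ranged from 1.36 to 3.83 over the alternatives. The lipoprotein-associated phospholipase gene Pla2g7 (1.34, 1.13 to 1.56), the complement gene C4b (1.16, 0.67 to 1.68) and Itch (0.96, 0.44 to 1.51) followed. The hemoglobin scavenger receptor gene Cd163 (-1.71, -2.18 to -1.25), Timd4, which binds dying cells (-1.22, -1.68 to -0.78), Pf4 (-1.13, -1.42 to -0.83) and Marco (-1.0, -1.23 to -0.77) were lower. With all deposited barcodes Timd4 turned to 0.24 and Marco to 0.01, and Cd163, Pf4 and Pla2g7 stood at -0.41, -0.43 and 0.69; with each library clustered alone C4b turned to -0.13.

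The Kupffer identity genes as a group were not lower: their median was 0.17 (0.09 to 0.23; percentile 99.0), with 3 of 18 members at least 1.5-fold lower, the receptors just named, and 3 as far higher, Id1 (0.82), Spic (0.67) and Cdh5 (0.61). The last is also an endothelial gene, and endothelial genes summed to 544 and 392.1 CPM in these cells. Markers that named the Kupffer-like class are members of the identity list. Cells low in them could fall outside the class, so this median cannot tell whether identity genes were kept. Monocyte genes had a median of -0.47 (-0.77 to -0.12; percentile 0.05) in these Kupffer-like cells, with 6 of 7 members below 0. Lipid-associated macrophage genes had a median of 0.00 (-0.12 to 0.09; percentile 50.6), with Fabp5 at -1.73 (-2.73 to -0.81) and Cd36 at 0.47 (0.19 to 0.76). Inflammatory genes had a median of 0.15 (0.01 to 0.30; percentile 87.3), with 5 of 20 at least 1.5-fold higher, among them Il1a (1.86, 0.90 to 2.95), Il1b (1.31, 0.98 to 1.66) and Cxcl10 (1.16, 0.54 to 1.81), and with Ccl9 at -0.88 (-1.55 to -0.22). Il1b was left out of the size ranking here because its level was under 0.2 of that in another class of the same library. Free RNA or doublets could therefore give its ratio. Dissociation stress genes were higher, with a median of 0.44 (0.35 to 0.60), above all random lists. Of 19 such genes, 6 were at least 1.5-fold higher, including Hspa1a (1.39) and Fosb (1.02). The stress median was 0.05 with the list genes that are no markers kept out of clustering, 0.07 with doublets kept, 0.12 at Leiden resolution 0.5, 0.16 with stricter cell filters and 0.17 with all deposited barcodes. With each library clustered alone, a Kupffer-like class of other extent gave -0.91 for the identity genes, 1.0 for the monocyte genes, 1.65 for the stress list, 1.54 for Fabp5, 1.04 for Ccl9, -0.02 for Spic and -0.59 for Cdh5. All deposited barcodes turned Id1 to -0.24 and Cd36 to -0.24, and stricter cell filters turned the inflammatory median to -0.14 and Cxcl10 to -0.39 and left Il1b at 0.13. The classes held 231 and 258 cells at median depths of 2171 and 1251.5 UMIs; on simulated counts for 1410 of their genes, 50% of genes planted at 1.5-fold and 97.0% of those at 2-fold passed the limit.

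Ly6C-high monocyte-like cells of the Trem2-/- library had higher monocyte genes and lower macrophage and antioxidant genes. All 15 monocyte genes were above 0, with a median of 0.40 (0.32 to 0.48), above all random lists, and 3 at least 1.5-fold higher: Chil3, a chitinase-like secreted protein (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564; 1689 against 894 CPM, 0.92, 0.86 to 0.98), Vcan (0.75) and F13a1 (0.59). The list includes markers that named the class, so its values also depend on which cells the class holds. The other genes named by size were the chemokine genes Cxcl1 (1.04, 0.86 to 1.23) and Ccl2 (0.88, 0.69 to 1.08) and the osteopontin gene Spp1 (0.79, 0.63 to 0.95) on the higher side, and Cd63 (-0.96, -1.11 to -0.82), the stress-induced cytokine gene Gdf15 (-0.92, -1.06 to -0.79) and the peroxidase gene Prdx1 (-0.66, -0.71 to -0.60) on the lower side. Spp1 turned to -1.29 with all deposited barcodes, and Cd63 and Prdx1 turned to 0.52 and 0.10, and Gdf15 fell to -0.12, with each library clustered alone. The median of the monocyte genes ranged from 0.09 to 0.86 over the alternatives.

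Iron and oxidative stress genes had a median of -0.50 (-0.54 to -0.38) in these monocyte-like cells, below all random lists, with 3 of 11 at least 1.5-fold lower: Srxn1 (-1.05), Prdx1 and the glutathione synthesis gene Gclc (-0.62). This median ranged from -0.62 at Leiden resolution 0.5 to -0.08 at resolution 2. Lipid-associated macrophage genes had a median of -0.23 (-0.29 to -0.16), below all random lists, with 6 of 23 at least 1.5-fold lower, among them Igf1 (-1.79, -2.30 to -1.31) and Mmp12 (-1.46, -1.90 to -1.04); the median turned to 0.39, Igf1 to 0.44 and Mmp12 to 2.38 when each library was clustered alone. Inflammatory genes had a median of 0.18 (0.15 to 0.22; percentile 99.99), with 5 of 22 at least 1.5-fold higher, among them Il1a (1.10) and Il6 (0.82), and Cxcl3 lower at -1.16; the median was 0.05 with all deposited barcodes. Of 5 measured neutrophil genes, which mark another cell type, the median was 0.32 (0.06 to 0.62; percentile 99.8), while their summed level was 363.6 against 469.9 CPM. Cxcl3 turned to 0.40 with all deposited barcodes, and Srxn1 to 0.19 and Gclc to 0.53 at Leiden resolution 2. The stress list stood at 0.12 (0.09 to 0.15; percentile 99.5), with Hspa1a at 1.02.

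T cell-like cells of the Trem2-/- library carried more transcripts of inhibitory receptors and effector molecules and less of interferon-response genes. By size, the costimulatory receptor gene Tnfrsf4 (154 against 48.0 CPM, log2 ratio 1.68, 1.41 to 1.95), the inhibitory receptor gene Lag3 (ENSMUSG00000030124, chromosome 6, 124904361 to 124911705; 169.8 against 62.1 CPM, 1.45, 1.22 to 1.69), Cd7 (1.42, 1.29 to 1.55) and the chemokine gene Ccl4 (1556 against 768 CPM, 1.02, 0.95 to 1.09) were highest. With the clusters weighted equally Tnfrsf4 fell to 0.16 and Lag3 to 0.54, and with each library clustered alone Cd7 fell to 0.49 and Ccl4 to 0.30. Within cluster 21, where its level was highest, Tnfrsf4 stood at 1111 and 1105 CPM (0.01, -0.40 to 0.44), and within clusters 2 and 4 its ratios were 1.15 and 1.31. Ly6c2 (-0.76, -0.85 to -0.67) and Isg15 (-0.59, -0.77 to -0.40) were lower. The class was made up of clusters 2, 4, 13 and 21 in shares of 27.0%, 45.6%, 22.3% and 5.20% in the Trem2-/- library and 21.8%, 36.4%, 39.9% and 1.98% in the Trem2+/+ library. Scaling of the T cell class mattered slightly: trimmed-mean scaling shifted all its log2 ratios by -0.09 and a total without abundant genes by -0.10.

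All 14 measured exhaustion and residency genes were above 0 in T cell-like cells. Their median was 0.53 (0.48 to 0.72), above all random lists, with 6 at least 1.5-fold higher, among them the checkpoint receptor genes Ctla4 (0.93, 0.79 to 1.07), Tigit (0.91, 0.77 to 1.06) and Pdcd1 (0.85, 0.69 to 1.0). Within clusters 2, 4, 13 and 21 the medians were 0.38, 0.41, 0.08 and 0.00, and with the clusters weighted equally 0.24, where Ctla4 stood at 0.09. Equal weight leans on cluster 21, which held only 60 cells in the Trem2-/- and 16 in the Trem2+/+ library. Cytotoxicity genes had a median of 0.41 (0.40 to 0.63), above all random lists, with 6 of 13 at least 1.5-fold higher, including Tnfsf10, which encodes the death ligand TRAIL (1.02, 0.67 to 1.39), Ifng (0.69, 0.53 to 0.86) and the granzyme gene Gzma (0.66, 0.60 to 0.72), whereas Gzmb stood at -0.09 (-0.19 to 0.01), kept that sign in 8 of 14 alternatives and was at -0.87 with each library clustered alone. Their medians within the clusters were -0.25, 0.23, 0.04 and -0.04. Interferon-response genes had a median of -0.30 (-0.44 to -0.22), below all random lists, with 5 of 17 at least 1.5-fold lower, among them Cxcl10 (-1.73, -2.04 to -1.43), Ifit3 (-1.72, -2.23 to -1.23) and Ifit1 (-1.16, -1.66 to -0.67), and Ifitm3 higher at 0.73. Their medians within the clusters were -0.87, -0.35, 0.01 and 0.09, and Cxcl10 stood at -0.70 with the list genes that are no markers kept out of clustering. Dissociation stress genes had a median of 0.30 (0.21 to 0.36) here, also above all random lists, with 19 of 20 above 0 and 2 at least 1.5-fold higher, Hspa1a (0.98) and Hspa1b (1.89).

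**Figure D4:**
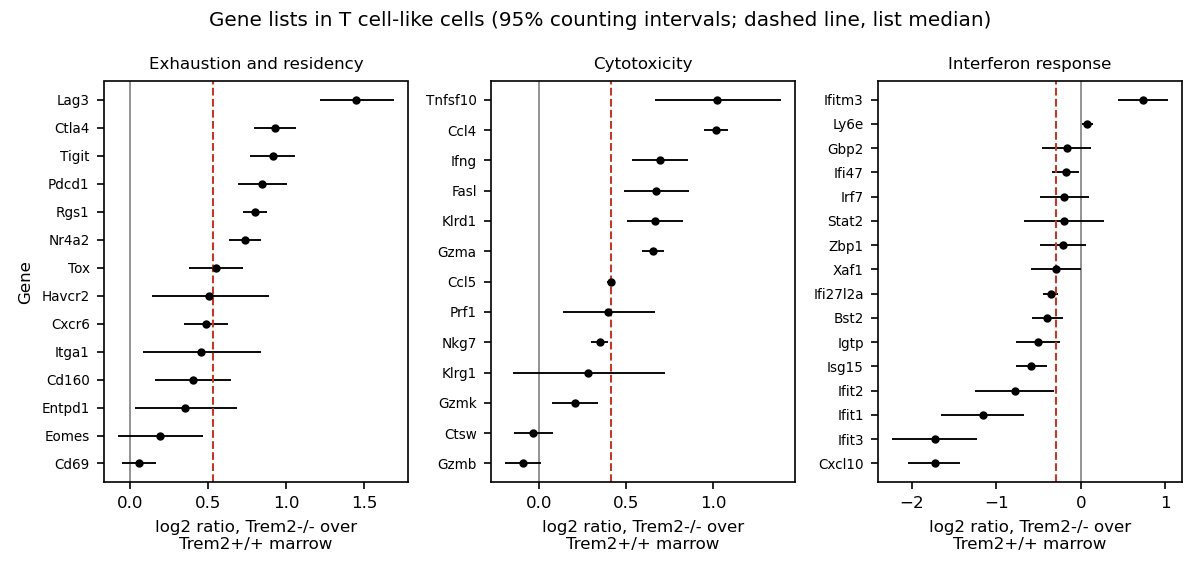
Log2 ratio of the Trem2-/- over the Trem2+/+ library in T cell-like cells (horizontal axis) for the measured genes of 3 lists, 1 panel per list, except 1 interferon-response gene that is not drawn but counts in the median; points are genes, solid lines their 95% counting intervals and dashed lines the list medians. The medians are 0.53 for exhaustion and residency genes, 0.41 for cytotoxicity genes and -0.30 for interferon-response genes.

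The T cell receptor beta segments used in the T cell-like class also differed between the libraries. A UMI of Trbv19 was found in 4.94% of cells (3.76 to 6.35) of the Trem2-/- library and in 25.9% (22.9 to 29.0) of those of the Trem2+/+ library. Trbv3 was found in 15.2% and 6.31%, Trbv12-2 in 11.2% and 5.45%, and Trbv1 in 9.97% and 3.22%. On simulated counts for 1311 genes of this class, 52.9% of genes planted at 1.5-fold and 100% of those at 2-fold passed the limit.

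NK/ILC1-like cells differed most in the chemokine gene Ccl1, at 45.0 against 465 CPM, a log2 ratio of -3.37 (-3.85 to -2.92). The granzyme gene Gzmc was lower as well (-0.92, -1.21 to -0.64). Eif3j1 (0.84), the cytokine receptor gene Il21r (0.79), the cytokine signalling inhibitor gene Socs1 (0.72) and Eif4a2 (0.69) were higher. Cytotoxicity genes had a median of 0.03 (-0.05 to 0.11; percentile 67.2), with 0 of 12 past 1.5-fold either way. The stress list stood at 0.16 (0.10 to 0.25; percentile 99.6). In B cell-like cells few genes passed the size rule: Sp140 (0.70), Vps37b (0.64) and the class I gene H2-Q7 (0.63) were higher and Sesn1 (-0.68) was lower. Their interferon-response list had a median of 0.06 (-0.14 to 0.29; percentile 64.7) and their stress list 0.09 (0.01 to 0.18; percentile 97.4).

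Conventional dendritic-like cells of the Trem2-/- library had more Cxcl9. In cDC1-like cells it stood at 320.5 against 76.3 CPM (log2 ratio 2.07, 1.81 to 2.34), beside Serpinb6b (0.68), with the sterol synthesis gene Fdps lower (-0.59). In cDC2-like cells Cxcl9 stood at 463 against 63.4 CPM (2.87, 2.53 to 3.23), beside the interferon-induced GTPase gene Gbp2 (1.83, 1.42 to 2.25), Cxcl10 (1.63, 1.30 to 1.97) and Nrip1 (0.77), with Ap1s2 lower (-0.73); over the alternatives the Cxcl9 ratio ranged from 1.64 to 4.96, and with all deposited barcodes Gbp2 and Cxcl10 fell to 0.94 and 0.93. As a group, interferon-response genes had medians of 0.13 (0.04 to 0.29; percentile 97.4) in cDC1-like and 0.10 (-0.09 to 0.24; percentile 88.6) in cDC2-like cells. The latter kept its sign in 8 of 13 alternatives and was -0.30 as a mean over cells. Inflammatory genes went in opposite directions, with a median of -0.26 (-0.42 to -0.09) in cDC1-like cells, where Ccl3 stood at -1.35 and Cxcl2 at -1.18, and 0.21 (0.14 to 0.30) in cDC2-like cells, where Cxcl2 stood at 1.14. Neutrophil genes moved with them, summing to 117 and 855 CPM in cDC1-like cells and to 294 and 72.1 CPM in cDC2-like cells. Removing the 5% of barcodes with the highest doublet scores turned the cDC1 inflammatory median to 0.20, and Cxcl2 to 0.65 in cDC1-like and -0.19 in cDC2-like cells. Stress lists stood at 0.07 (0.02 to 0.16) and 0.04 (-0.05 to 0.10), within the central 95% of random lists.

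Neutrophil-like cells of the Trem2-/- library differed in single interferon-response and chemokine genes in both directions. Ifi47, an interferon-inducible GTPase gene, stood at 195 against 47.2 CPM (log2 ratio 2.05, 1.63 to 2.48), followed by Cwc25 (1.01), the cell cycle inhibitor gene Cdkn1a (0.96) and Gbp2 (0.89). Ifi27l2a (-0.85), Rsad2 (-0.80) and the chemokine genes Ccl4 (-0.72, -0.77 to -0.68) and Ccl3 (-0.71, -0.79 to -0.64) were lower, and with each library clustered alone Ccl4 turned to 0.06, Ccl3 fell to -0.07 and Rsad2 to -0.05. The interferon-response list as a whole had a median of -0.08 (-0.31 to 0.06; percentile 22.3), with 4 of 23 members at least 1.5-fold higher, including Igtp (1.33), and 7 as far lower, including Ifit1 (-1.58) and Ifit3 (-1.28). Its stress list stood at -0.09 (-0.17 to -0.02; percentile 7.21), and endothelial genes summed to 222 and 107 CPM. Clusters 8 and 23 made up 68.3% and 31.7% of the class in the Trem2-/- library and 57.2% and 42.8% in the Trem2+/+ library.

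In endothelial-like cells, whose marrow origin is not given by the labels, the retinoic acid hydroxylase gene Cyp26b1 was highest at 1083 against 493 CPM (log2 ratio 1.13, 1.03 to 1.24). The stress-responsive transcription factor genes Jun (0.65, 0.50 to 0.81) and Klf4 (0.62, 0.36 to 0.88) were higher and the Wnt pathway enhancer gene Rspo3 was lower (-0.85, -1.01 to -0.68), though it stood at -0.01 with the clusters weighted equally. Dissociation stress genes had a median of 0.33 (0.26 to 0.45), above all random lists, with 7 of 20 at least 1.5-fold higher, including Egr1 (1.15) and Fos (0.90). Interferon-response genes had a median of -0.26 (-0.31 to -0.18), below all random lists, with 1 of 24 at least 1.5-fold lower, Ifi27l2a (-0.68), which turned to 0.24 with each library clustered alone. Genes of other cell types differed beside these lists: B cell genes had a median of -1.84 (-2.27 to -1.37), with 3 of 3 at least 1.5-fold lower, hepatocyte genes 0.25 (percentile 99.4) and erythroid genes 0.33 (percentile 99.3), and neutrophil genes summed to 58.5 and 260.1 CPM. Clusters 0 and 1 made up 67.4% and 32.6% of this class in the Trem2-/- library and 57.7% and 42.3% in the Trem2+/+ library.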

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

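Of the tests on Trem2 below, those of free RNA, of the UMIs in cells with several and of the cells with at least 1 UMI were chosen only after the result was seen; so were the tests of depth and dilution for the macrophage share, the clustering setting behind its test of cluster borders, the test of cluster mix in T cells, and the comparison of Ccl4 between classes.

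Ccl4, a chemokine gene, drew attention because its ratios had opposite signs in 2 classes of the same libraries. It was higher in T cell-like cells of the Trem2-/- library, with a log2 ratio of 1.02 (0.95 to 1.09), and lower in neutrophil-like cells, at -0.72 (-0.77 to -0.68), a gap of 1.74. The difference was not tested, since each group holds 1 library, and with each library clustered alone the ratios were 0.30 and 0.06.

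The Trem2-/- library still held 154 Trem2 UMIs, of which 99 lay in macrophage-like cells. Free RNA is argued against as their main source, because the Trem2 level in macrophage-like cells was 138-fold (45.7 to 679) that in T, B, NK and neutrophil classes of the same library, which held 3 UMIs. An even low level in every macrophage-like and Kupffer-like cell would give 13 to 24 cells with at least 2 UMIs, and 17 were seen; these held 75 UMIs where 28 to 53 would be drawn, but 48 of them lay in 4 cells, and without those the other 13 held 27 where 8 to 25 would be drawn. A minority of cells at the Trem2+/+ level, such as surviving recipient macrophages, may contribute: 8.83% of cells would give 8 to 23 cells with at least 2 UMIs. The 61 cells with a UMI exceeded the 11 to 28 of that model. The highest count in a cell was 18 UMIs, against 8 over 10000 draws of the even level. Neither model alone, as simulated, gave all of these counts. Since both assume a profile, a part from each stays open. Transcripts from an undeleted part of the gene in the donor cells stay open and untested.

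The share of macrophage-like cells was lower in the Trem2-/- library, with a log2 ratio of -1.95. Cluster borders set by genes that differ between the libraries are argued against as the cause for the pooled phagocyte classes, whose ratio was -0.96 (-1.06 to -0.86) with the macrophage and MHC class II lists kept out of clustering. Clusters of that setting were still named by markers from those lists, among them Gpnmb, so the test covers borders and not names. Barcodes of low depth are argued against by a macrophage-like ratio of -1.82 (-2.02 to -1.61) among cells with at least 1000 UMIs, and dilution by more T and endothelial cells by a ratio of -1.84 (-2.05 to -1.63) per B, NK, neutrophil, dendritic and Kupffer-like cell (0.119 against 0.426). How the pooled class divides into Kupffer-like, macrophage-like and monocyte-like cells is not settled by these tests, since clustering each library alone gave no macrophage-like cells in the Trem2-/- library and a pooled ratio of -0.59. An effect of the marrow genotype and a difference between 2 sorts or pools of mice may both account for the lower share, and with 1 library per group neither was tested.

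Exhaustion and residency genes were higher in T cell-like cells of the Trem2-/- library, with a median log2 ratio of 0.53. Cells seen to carry any of the 4 beta segments that differ most are argued against as the whole cause. Without them the median was 0.45 (0.38 to 0.78), with 691 and 489 cells left. Clones were not identified, and cells with other segments that differed, such as Trbv2 (7.71% and 2.23%), were kept. Expanded clones therefore stay open. Another mix of T cell clusters may contribute. With clusters weighted equally the median was 0.24 (0.10 to 0.39), between the values set for and against that explanation. Equal weight counts cluster 21, with only 60 cells in the Trem2-/- and 16 in the Trem2+/+ library, as much as the larger clusters. The medians within clusters 2, 4, 13 and 21 were 0.38, 0.41, 0.08 and 0.00. An effect of the marrow genotype on T cells remains open and untested.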

How the results depend on the processing

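Alternatives that removed the top 5% of doublet scores, kept the macrophage and MHC class II lists out of clustering, weighted clusters equally or took ratios from cells with at least 1000 UMIs were chosen only after the data were seen. No paired analysis was possible because each group holds 1 library. Every alternative that gave a value kept the lower Trem2 level, which ranged from -5.08 to -5.02 over all cells and from -5.41 to -3.93 in macrophage-like cells. Alternatives that only clustered anew held the same cells, so the all-cell ratio could not move in them. The main macrophage-like value of -3.73 lay outside the range of its alternatives. The sign was also kept for the pooled phagocyte share (-0.99 to -0.59), the macrophage-like share (-1.98 to -1.29), the endothelial-like share (0.62 to 0.76) and the T cell-like share (0.13 to 0.83). In macrophage-like cells it was kept for the lipid-associated (-0.81 to -0.42), MHC class II (0.45 to 0.57), inflammatory (0.14 to 0.70) and iron (-0.54 to -0.28) medians. Medians within single clusters were not among these alternatives, and some lay outside those ranges. In clusters 15, 16 and 19 they were -0.18, -1.0 and -0.29 for lipid-associated and 0.24, 0.81 and 0.57 for MHC class II genes. For inflammatory genes they were 0.26, -0.56 and 0.47, and for iron genes -0.18, -0.57 and -0.20. In T cell-like cells the sign was kept for exhaustion (0.24 to 0.70) and cytotoxicity genes (0.24 to 0.65). The Kupffer-like, monocyte-like and neutrophil-like shares and the lipid-associated median in monocyte-like cells turned under some alternatives, as did the B cell-like share, which was near 0 throughout (-0.036 to 0.026) and kept its sign in 5 of 11. Of the values of single named genes over all alternatives, 1578 stayed within the counting interval, 533 moved beyond it and 82, whose interval excluded 0, turned sign; for list medians of secondary rank these numbers were 516, 92 and 14, and for shares of other classes 78 stayed and 7 moved. Counting also values whose interval held 0, 114 of 2193 single-gene values, 40 of 622 of these medians and 15 of 85 of these shares lay on the other side of 0. Of the main list medians, 82 values stayed within the counting interval, 48 moved beyond it and 3 turned sign. For the main shares these numbers were 70, 19 and 3, and of the Trem2 values 29 stayed and 17 moved. Which genes were named depended on the CPM limit: with it halved and doubled, 16 and 19 of the 24 genes named in macrophage-like cells stayed named, 5 and 4 of 8 in Kupffer-like, 5 and 3 of 7 in T cell-like, 3 and 4 of 7 in monocyte-like, and 1 and 5 of 8 in neutrophil-like cells. These numbers were 3 and 3 of 4 in endothelial-like, 1 and 2 of 6 in NK/ILC1-like, 1 and 1 of 4 in B cell-like, 1 and 1 of 5 in cDC1-like and 3 and 1 of 5 in cDC2-like cells. Leiden resolution 0.5 gave no macrophage-like class and clustering each library alone left 0 such cells in the Trem2-/- library, so neither gave ratios within that class; classes of a single cluster have no equally weighted value. Depth limits the shares of cells with a Trem2 UMI, as the thinned values show. Apart from thinning, which leaves fewer UMIs per cell, the cause of the changes below was not tested; all values are log2 ratios or median log2 ratios unless given in percent.

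Thinned to 1000 UMIs, a Trem2 UMI was seen in 5.86% and 40.6% of macrophage-like cells of the Trem2-/- and Trem2+/+ libraries, 2.37% and 26.1% of Kupffer-like cells, and 0% (0 of 463 cells, exact upper bound 0.794%) and 12.6% of monocyte-like cells. Thinned to 2000 UMIs, the shares were 6.83% in macrophage-like and 2.48% in Kupffer-like cells of the Trem2-/- library, and 1.54% and 21.7% in monocyte-like cells of both.

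With all deposited barcodes, the share ratio was -1.03 for Kupffer-like and -1.29 for macrophage-like cells. In macrophage-like cells Trem2 was -5.41, Cd72 -1.04, Cd81 -0.27, Vcam1 -0.11, Apoe -0.43, Slc7a11 0.030, Ccl12 -1.38, Olr1 0.25, C1qa -0.26, C1qc -0.47, Vsig4 -1.05, Pgam1 0.12 and Pkm 0.0042. The medians there were -0.81 for lipid-associated, 0.70 for inflammatory, -0.26 for efferocytosis and -0.36 for Kupffer identity genes. In Kupffer-like cells Timd4 was 0.24, Marco 0.013, Id1 -0.24, Cd36 -0.24, Cxcl9 0.041 and the stress median 0.17. In monocyte-like cells Spp1 was -1.29, Cxcl3 0.40 and the lipid-associated median -0.070. The T cell cytotoxicity median was 0.40.

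With at least 500 genes and at most 5% mitochondrial UMIs, the Kupffer-like share was -0.36, the pooled share -0.79, Trem2 in macrophage-like cells -4.06 and Lyz1 -0.092. In Kupffer-like cells Cxcl10 was -0.39, the inflammatory median -0.14 and the stress median 0.16. With doublets kept, Kupffer-like cells had Trem2 at -3.05, Id1 at -0.18, Cxcl10 at -0.50, inflammatory genes at -0.045 and stress genes at 0.073, and T cell cytotoxicity was 0.40. This setting added only 7 barcodes, but clustering anew changed the unnamed cells from 850 and 575 to 391 and 415. Its values therefore show how far class borders move with almost the same cells, more than an effect of doublets.

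With the top 5% of doublet scores removed, the shares were 0.29 for Kupffer-like, -0.23 for monocyte-like and -1.73 for macrophage-like cells. The medians were -0.51 for lipid-associated, 0.45 for MHC class II and -0.36 for iron genes in macrophage-like cells, -0.035 for lipid-associated and 0.25 for monocyte genes in monocyte-like cells, 0.65 for T cell cytotoxicity and 0.20 for cDC1 inflammatory genes. Cxcl10 in Kupffer-like cells was -0.15, Cxcl3 in monocyte-like cells 0.82, and Cxcl2 0.65 in cDC1-like and -0.19 in cDC2-like cells.

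At Leiden resolution 0.5, the shares were -1.01 for Kupffer-like, -0.90 for monocyte-like and 0.83 for T cell-like cells. Monocyte-like cells had Spp1 at -0.46, lipid-associated genes at -0.83 and monocyte genes at 0.86. Kupffer-like cells had stress genes at 0.12, Id1 at -0.30 and Cxcl9 at 0.16. T cell cytotoxicity was 0.36 and Cxcl2 in cDC1-like cells 0.52. At resolution 2, the monocyte-like share was 0.43, and Trem2 was -4.07 in macrophage-like and -2.85 in Kupffer-like cells. Macrophage-like cells had inflammatory genes at 0.48, iron genes at -0.38, Olr1 at 0.12 and Lyz1 at -0.024. Monocyte-like cells had Spp1 at -1.21, lipid-associated genes at 0.10, monocyte genes at 0.088, Srxn1 at 0.19, Gclc at 0.53 and Mmp12 at 1.25. Kupffer-like stress genes were 0.29 and Cxcl9 0.42, T cell cytotoxicity 0.37 and Cxcl2 in cDC2-like cells -0.049.

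With each library clustered alone, the shares were 2.0 for Kupffer-like, -0.14 for monocyte-like, 0.13 for T cell-like and 0.67 for neutrophil-like cells and -0.59 for the pooled classes. In Kupffer-like cells identity genes were -0.91, monocyte genes 1.0, stress genes 1.65, C4b -0.13, Spic -0.019, Cdh5 -0.59, Fabp5 1.54, Cd36 -0.13, Ccl9 1.04 and Cxcl9 0.63. In monocyte-like cells Trem2 was -3.93, lipid-associated genes 0.39, monocyte genes 0.18, Cd63 0.52, Prdx1 0.10, Igf1 0.44, Mmp12 2.38 and Cxcl3 0.34. T cell exhaustion was 0.46 and cytotoxicity 0.25, Ccl4 in neutrophil-like cells 0.056 and Ifi27l2a in endothelial-like cells 0.24.

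With list genes that are no markers kept out of clustering, the shares were -0.23 for monocyte-like, 0.82 for T cell-like and -1.66 for macrophage-like cells. Kupffer-like cells had inflammatory genes at -0.14, stress genes at 0.049, Id1 at -0.024, Cd36 at -0.44, Cxcl10 at -0.79 and Cxcl9 at 0.19. Monocyte-like cells had lipid-associated genes at 0.023, monocyte genes at 0.26 and Cxcl3 at 0.60, and T cell cytotoxicity was 0.38. With the macrophage and MHC class II lists kept out, the shares were -0.68 for Kupffer-like, 0.22 for monocyte-like and -1.49 for macrophage-like cells. Macrophage-like cells then had Trem2 at -4.53, lipid-associated genes at -0.77, inflammatory genes at 0.50, efferocytosis genes at -0.059, TREM2 partners at -0.0017, Cd72 at -0.63, Lyz1 at -0.018 and Vcam1 at -0.28. They had Apoe at -0.41, Slc7a11 at 0.12, Ccl12 at -0.99, Oasl1 at -0.22, Olr1 at 0.17, C1qc at -0.10, Pgam1 at 0.074 and Pkm at 0.030. Kupffer-like cells had Timd4 at 0.054, stress genes at 0.24, Id1 at -0.28, Spic at -0.034, Cd36 at -0.20 and Cxcl9 at 0.39. Monocyte-like cells had lipid-associated genes at -0.027, monocyte genes at 0.19, Srxn1 at 0.10, Gclc at 0.28 and Cxcl3 at 0.0038.

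With TMM scaling, T cell exhaustion was 0.43 and cytotoxicity 0.32, and with the total without abundant genes 0.40 and 0.31. As a mean over cells, Kupffer-like stress genes were 0.32, and macrophage-like cells had lipid-associated genes at -0.42, inflammatory genes at 0.14, iron genes at -0.28 and Nlrp3 at -0.026. With clusters weighted equally, T cell exhaustion was 0.24 and cytotoxicity 0.24. Macrophage-like cells then had lipid-associated genes at -0.43, inflammatory genes at 0.17, interferon-response genes at -0.16, efferocytosis genes at -0.10, Kupffer identity genes at -0.32, TREM2 partners at -0.081 and iron genes at -0.33. Single genes there were Anxa2 at 0.29, Apoe at -0.17, C1qa at -0.0013 and Pkm at 0.014.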

Other observations

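The test of interferon-gamma-inducible genes and the comparison of Cxcl9 across classes were chosen only after single-gene ratios had been seen, and the bound on its medians after those had been seen.

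Glycolysis genes, fixed as a list in advance, had medians above 0 in 9 of the 10 classes, and above the central 95% of random lists in 3 of them. Dissociation stress genes, which mark handling of the cells, were also above 0 in 9 of the 10 classes, and above the central 95% in 6, with a median of -0.09 in neutrophil-like cells. The list median was 0.25 (0.12 to 0.39) in cDC1-like cells, above all random lists, 0.17 (0.12 to 0.25; percentile 99.9) in monocyte-like cells, 0.16 (0.02 to 0.30; percentile 99.1) in neutrophil-like cells and 0.24 (0.04 to 0.45; percentile 96.3) in Kupffer-like cells. It was 0.19 (percentile 94.6) in T cell-like, 0.17 (95.1) in NK/ILC1-like, 0.15 (94.6) in cDC2-like, 0.12 (83.8) in B cell-like and 0.03 (52.7) in endothelial-like cells. In macrophage-like cells it was -0.03 (-0.12 to 0.09; percentile 40.6). The sign was kept in every alternative in 8 of the 10 classes, the exceptions being endothelial-like cells with 14 of 16 and macrophage-like cells with 7 of 14.

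Gapdh, which encodes a central glycolytic enzyme, was higher in each of the 10 classes under every alternative that gave a value, from 0.22 (0.05 to 0.38) in endothelial-like cells to 0.70 (0.60 to 0.80; 666 against 411 CPM) in T cell-like cells. Hk2, whose product starts glycolysis, was higher in Kupffer-like (1.44, 0.82 to 2.10; 0.58 to 1.47 over the alternatives), monocyte-like (0.75, 0.51 to 0.98) and macrophage-like cells (0.68, 0.41 to 0.94). In macrophage-like cells Pgam1 (-0.53, -0.68 to -0.38) and Pkm (-0.27) were lower, and both turned above 0 with all deposited barcodes.

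Cxcl9 was higher in the Trem2-/- library in other classes than the dendritic and macrophage-like cells, though not in all. The log2 ratio was 2.07 (1.36 to 2.84; 69.5 against 16.5 CPM) in neutrophil-like cells and 0.66 (0.53 to 0.79; 321 against 204 CPM) in monocyte-like cells, but 0.05 (-0.12 to 0.22) in endothelial-like cells. The neutrophil-like level was under 0.2 of the 463 CPM in cDC2-like cells of the Trem2-/- library, so free RNA or doublets could give it. In Kupffer-like cells it was -0.62 (-1.09 to -0.15), and it turned to 0.63 with each library clustered alone.

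More interferon-gamma response across the classes of the Trem2-/- library was considered as a candidate explanation for the higher Cxcl9. It was tested on 18 other interferon-gamma-inducible genes, of which Ciita is also in the MHC class II list. Their median was above the central 95% of random lists in 2 of 10 classes and below it in 0: macrophage-like cells (0.34, 0.22 to 0.43; percentile 99.99) and neutrophil-like cells (0.22, 0.10 to 0.44; percentile 98.9). It was above 0 in 9 of the 10 classes, with 0.18 (percentile 95.6) in B cell-like, 0.14 (91.8) in cDC2-like, 0.13 (83.1) in Kupffer-like, 0.12 (96.3) in monocyte-like, 0.10 (82.7) in NK/ILC1-like, 0.04 (22.2) in T cell-like and 0.03 (63.8) in cDC1-like cells, and -0.05 (9.8) in endothelial-like cells. These values neither show nor exclude a small response shared by most classes.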
